A study of Mus musculus with 24 samples.

How the data were processed

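RNA-seq libraries from mouse cecal content were compared between 2 background microbiotas, OMM and ASF. Groups came from the microbiota and condition labels of the 24 samples. Replicate numbers follow sample order within a group and pair no samples. The 8 control samples were not analysed here. Total RNA was extracted from flash-frozen content and made into Illumina libraries, per the labels' protocols, which mention no removal of ribosomal RNA and no strand setting.

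The deposited values are whole-number counts of reads per locus tag, 1 table per organism and 1 column per library, with no normalisation. Trimmomatic 0.39, FastQC, Bowtie2 2.3.5 and HTSeq 0.11.2 were used by the authors, per the submitters' processing notes, which give no settings. The genome build and annotation are not given in the sources used here. Reads that fit several places, including copies of ribosomal RNA genes and sequences shared with other gut bacteria, can be lost or placed on 1 tag in such counting, so levels of tags of that kind are uncertain. Each column was matched to its sample by the title. A mouse reference was given, and 0 of the 10119 tags matched its tables. Tags were therefore reported by identifier, at most 2 higher and 2 lower per organism, and the 46 gene lists fixed beforehand, the comparison of the 2 organisms gene by gene and the share of conserved features could not be run.

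Each organism was tested with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM scaling, quasi-likelihood F test, Benjamini-Hochberg adjustment and a threshold of adjusted p below 0.05. Log2 fold changes are OMM minus ASF, and the standard error was taken as the absolute log2 fold change divided by the square root of F. Levels per library are log2 CPM after TMM scaling, with edgeR's default prior count. The test, the samples and the naming rule were fixed before the data were examined. The rule took tags past the threshold whose OMM and ASF values do not overlap and whose mean level is at or above the median of the tags tested, and named the 2 with the largest change in each direction. In E. coli 18 higher and 15 lower tags were eligible, in Salmonella 5 and 2. A tag with 3 or fewer OMM counts was given as a ratio of summed counts, with an exact binomial interval.

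On simulated counts with 200 changed tags, the same code recovered 8.7% of 2-fold, 71.7% of 4-fold and 100% of 8-fold changes among 1579 E. coli tags, with 0.647% of unchanged tags called. Among 620 Salmonella tags it recovered 18.6%, 90.7% and 100%, with 0.901% of unchanged tags called. Changes near 2-fold were thus mostly not called even in simulated counts. The simulation gave every tag the same dispersion and all libraries the same mean profile, with no evenly spread libraries. Recovery was counted only over tags that passed the filter again. The rates may thus be lower in the real libraries, and they do not measure what those libraries can call.

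Library totals and shares were compared with exact two-sided permutation tests over 70 arrangements (Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3; plots with matplotlib 3.10.9). Shares of single libraries have Wilson 95% intervals. A count of 0 allows up to 3 counts, which is 0.000333% to 0.00261% of a library. To compare libraries at equal depth, counts outside the abundant tags were thinned to 32023 (E. coli) and 12216 (Salmonella), as the mean of 20 draws. Replicates were compared by a chi-square test over tags. Its value per degree of freedom was 7.06 to 135 over the pairs, so no pair looked like 1 library deposited more than once. This does not show that the libraries came from separate mice.

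Sample titles hold a number and an S number. In 8 libraries with counts the S number is the first number minus 1 (up to 13) or minus 2 (from 15), which was read as a shared sequencing run. This holds for 2 OMM and 2 ASF E. coli libraries, and for all 4 ASF and no OMM Salmonella libraries. S numbers repeat among the libraries outside the series, which may thus come from several runs. The series as a covariate and the fit outside it therefore do not hold the run constant. Alternatives fixed beforehand were RLE size factors, DESeq2 1.42.0, no filter (at least 1 count), a filter at fixed counts (10 counts in 4 libraries and a total of 100), meant to be stricter, which tested more E. coli tags than filterByExpr (1825 against 1680) and fewer Salmonella tags (687 against 791), a 2-fold minimum, leaving out each library, and for E. coli the title series as a covariate or as 2 separate fits. Leaving out the evenly spread libraries, or the tags with a mean share of at least 1%, was added after seeing the data.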

Results

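RNA from the cecal content of gnotobiotic C57BL/6 mice, animals whose gut microbes are a defined set, was sequenced. The mice carried a background microbiota that the labels call OMM or ASF. These are the usual abbreviations of Oligo-Mouse-Microbiota and altered Schaedler flora, which the labels do not spell out. Within each background the labels name mice with E. coli Mt1B1, mice with Salmonella M2702 and controls with neither, in 6 groups of 4 samples. The deposited Salmonella table is named for M7202 instead, and its columns were matched to samples by title. The 8 control samples were not analysed here. The 16 other libraries had read counts per locus tag, 8 on 5030 tags of the E. coli strain and 8 on 5089 tags of the Salmonella strain. The design thus asks which transcripts of each of these gut bacteria differ in level between an OMM and an ASF background.

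Total counts per library ranged from 115013 to 899854. OMM E. coli libraries held fewer counts than ASF E. coli libraries, 305930 ± 52929 against 656350 ± 178899 (SD, n = 4 each; exact two-sided permutation p = 0.0286, the smallest that 70 arrangements allow; Benjamini-Hochberg p = 0.0858 over 12 tests). The OMM mean was also below the ASF mean in both sets of libraries split by the number series in the sample titles, with OMM minus ASF differences of −202376 counts inside the series and −498464 outside it (n = 2 per background in each, not tested). Salmonella totals were 177423 ± 56936 in OMM and 219765 ± 173331 in ASF, a difference within the spread between libraries (n = 4 each, exact permutation p = 0.886). Its direction rested on ASF replicate 3, with 476703 counts: the OMM minus ASF difference of −42342 became 43305 without that library. In each organism 7 tags held a mean of at least 1% of a library each, and together they took 56.5% to 92.9% of a library's counts. The Wilson 95% interval of this share, or of that of a library's largest tag, was at most ± 0.29 percentage points, which covers counting error only. Counts outside these 7 tags, which measure all other tags, ranged from 32023 to 269184 in the E. coli libraries and from 12216 to 207319 in the Salmonella libraries. In E. coli the backgrounds did not overlap, with 32023 to 69080 in OMM and 131320 to 269184 in ASF (exact permutation p = 0.0286; Benjamini-Hochberg p = 0.0858 over the same 12 tests). Low OMM counts on these other E. coli tags thus rest on shallower libraries. Nothing in the labels says that each library came from a separate mouse, so p-values measure the spread between these samples, which may be technical.

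In the E. coli libraries, counts on a small set of very abundant tags differed between the OMM and ASF backgrounds. Whether these counts are E. coli transcripts or reads of other bacteria could not be told here. Of the 7 abundant tags, 4 rose in OMM and together held 53.8% ± 18.3 of OMM counts against 1.09% ± 0.484 of ASF counts (SD, n = 4 each). These 4 were chosen by their calls in the same libraries. Another 1 of the 7, called the dominant ASF tag below, held 67.3% ± 10.7 of counts in ASF and 24.9% ± 9.94 in OMM. Its mean share was the largest of the 7 in OMM as well. Among all 1680 tags tested, 22 were higher and 36 lower in OMM at an adjusted p below 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), and each of these 58 differed by at least 2-fold.

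**Figure D1:**
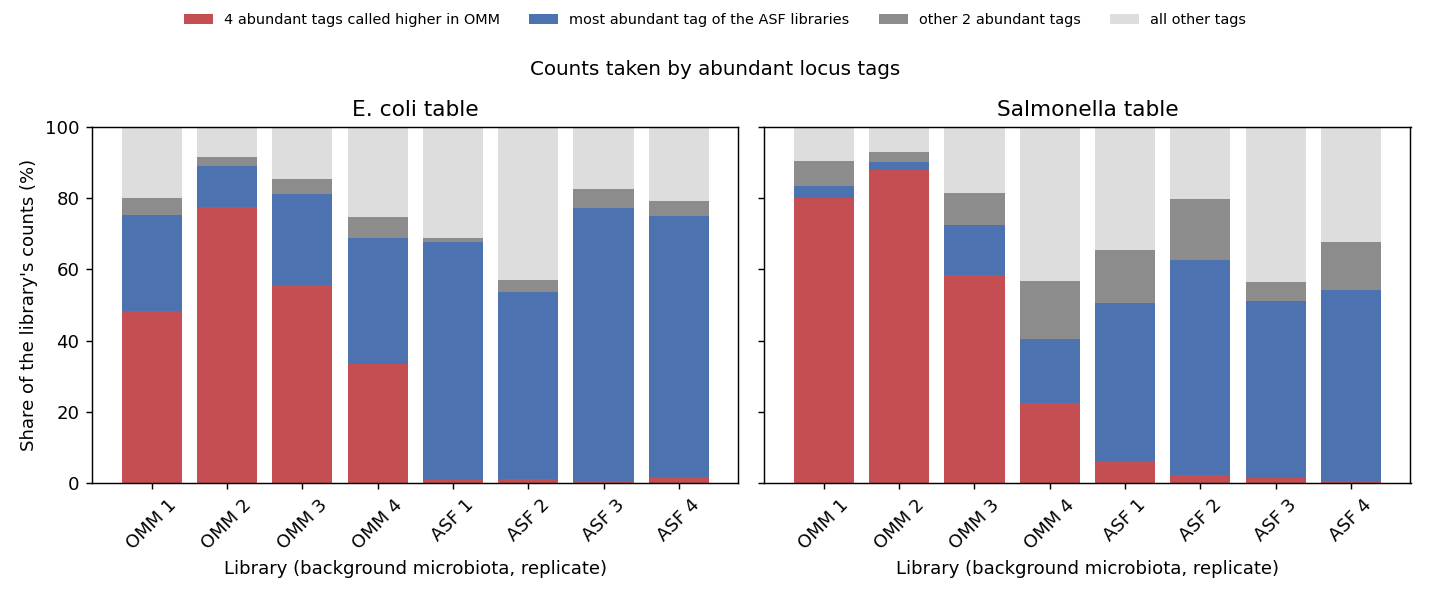
Share of each library's counts (y axis, percent) taken by abundant locus tags, 1 stacked bar per library (x axis), E. coli libraries on the left and Salmonella libraries on the right. The 4 tags that rose in OMM took 33.5% to 77.5% of counts in the OMM E. coli libraries and 0.514% to 1.67% in the ASF ones, and in Salmonella 22.6% to 88.0% against 0.786% to 6.28%.

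The files give locus tags without gene names, so the E. coli tags are named by identifier only. DBZ19_RS06225, at 15.77 ± 2.24 normalised log2 CPM in OMM and 9.67 ± 0.59 in ASF (SD, n = 4 each), had a log2 fold change of 7.32 (SE 1.26, edgeR adjusted p = 0.00397). Its OMM level was uneven: OMM replicate 3 held 69173 counts and the other 3 OMM libraries 5194 to 11814, and without replicate 3 the log2 fold change was 5.53. DBZ19_RS06195 stood at 17.72 ± 1.35 in OMM and 11.37 ± 0.61 in ASF, a log2 fold change of 6.78 (SE 1.01, edgeR adjusted p = 0.00121), and at 5.84 without OMM replicate 2. The tags that fell furthest under the naming rule had almost no counts in OMM. DBZ19_RS09480 had 2 counts over the 4 OMM libraries and 315 over the 4 ASF libraries, an ASF to OMM ratio of 45.1 after scaling to the counts outside the abundant tags (exact 95% counting interval 12.4 to 374; edgeR adjusted p = 0.00121). DBZ19_RS09465 had 2 and 285 counts, a ratio of 40.8 (interval 11.2 to 338; edgeR adjusted p = 0.000694). Both OMM counts of DBZ19_RS09480 came from replicate 2, and those of DBZ19_RS09465 from replicates 2 and 4. The fitted log2 fold changes moved with the library left out: that of DBZ19_RS09480, −5.46, became −8.91 without OMM replicate 2, −4.87 without replicate 1 and −4.80 without replicate 4, and that of DBZ19_RS09465, −5.30, became −4.70 without OMM replicate 1. Inside and outside the title series the log2 fold changes were 7.03 and 7.74 for DBZ19_RS06225, 8.67 and 5.14 for DBZ19_RS06195, −3.21 and −8.93 for DBZ19_RS09480, and −4.44 and −5.26 for DBZ19_RS09465.

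The dominant ASF tag of E. coli differed between backgrounds as a share of counts (exact two-sided permutation p = 0.0286, n = 4 each; Benjamini-Hochberg p = 0.04 over 14 tests). Inside the title series its OMM minus ASF difference was −40.5 percentage points. Outside the series, where libraries may come from several runs, the difference was −44.4 (n = 2 per background in each, not tested). After TMM scaling the log2 fold change of this tag was −1.01 (SE 0.67, edgeR adjusted p = 0.385), not past the threshold. Shares of a library sum to a fixed total, so the rise of the 4 abundant tags in OMM lowers all other shares. The fall of the dominant share is thus not independent of that rise, and how much of it goes beyond the rise was not measured. The 4 abundant tags that rose had edgeR adjusted p from 0.00113 to 0.00397. With no filter on low counts, 0 of these 4 were called.

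ASF E. coli replicates 1 and 2 stood apart from every other E. coli library. Outside the abundant tags, 50% of their counts lay on 21.3% of tags, against 1.67% to 4.16% in the other 6 libraries. Without these 2 libraries, an alternative chosen after seeing the data, 33 tags were higher and 41 lower in OMM, and 37 of these 74 were among the 58. The 4 libraries inside the title series, which include both of these, gave 1894 calls (701 higher and 1193 lower; 42 of them among the 58) and the 4 outside it gave 23 (13 higher and 10 lower; 14 among the 58), with 2 libraries per background in each. The ASF libraries inside the series are evenly spread and those outside it are not. Within ASF the series and the even spread thus cannot be told apart, also in the fit with the series as a covariate. The count of 58 became 37 without OMM replicate 2, 38 without OMM replicate 4, 33 without ASF replicate 2 and 134 without ASF replicate 3, and it was 269 with DESeq2 (86 higher, 183 lower), 95 with the title series as a covariate (41 higher, 54 lower), 38 with no filter on low counts and 92 with a filter at fixed counts. The calls of DBZ19_RS06225 and DBZ19_RS06195 ended with no filter on low counts (edgeR adjusted p = 0.0725 and 0.109, at log2 fold changes of 7.50 and 7.02) and in the 4 libraries outside the series (0.123 and 0.0771).

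In the Salmonella libraries, counts on abundant tags again differed between backgrounds, on other tags of another genome. Reads of other bacteria could not be told apart from Salmonella transcripts here either. Of the 7 abundant Salmonella tags, 4 rose in OMM and together held 62.2% ± 29.2 of OMM counts against 2.73% ± 2.46 of ASF counts (SD, n = 4 each). The dominant ASF tag held 51.9% ± 6.71 of counts in ASF and 9.42% ± 7.74 in OMM. Of 791 tags tested, 6 were higher and 8 lower in OMM (edgeR, adjusted p below 0.05), each by at least 2-fold.

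SL1344_RS01260 stood at 17.69 ± 1.97 normalised log2 CPM in OMM and 11.85 ± 1.64 in ASF (SD, n = 4 each), a log2 fold change of 5.98 (SE 1.17, edgeR adjusted p = 0.00535). SL1344_RS13645, which alone held 37.6% ± 18.1 of OMM counts and 1.63% ± 1.45 of ASF counts, had a log2 fold change of 5.92 (SE 1.19, edgeR adjusted p = 0.00583). Without OMM replicate 2 the log2 fold changes of these tags were 5.32 and 5.30. Lower in OMM were SL1344_RS02335, at 4.12 ± 1.16 in OMM and 7.69 ± 0.14 in ASF, and SL1344_RS23650, at 5.75 ± 0.47 and 8.12 ± 1.05. Their log2 fold changes were −3.22 (SE 0.56, edgeR adjusted p = 0.00306) and −2.74 (SE 0.59, edgeR adjusted p = 0.00993). For SL1344_RS02335 the OMM libraries held 0, 0, 2 and 17 counts, and without OMM replicate 4 its log2 fold change was −4.43. For SL1344_RS23650, ASF replicate 3 held 431 counts against 23 to 35 in the other ASF libraries, and without it the log2 fold change was −1.97.

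**Figure D2:**
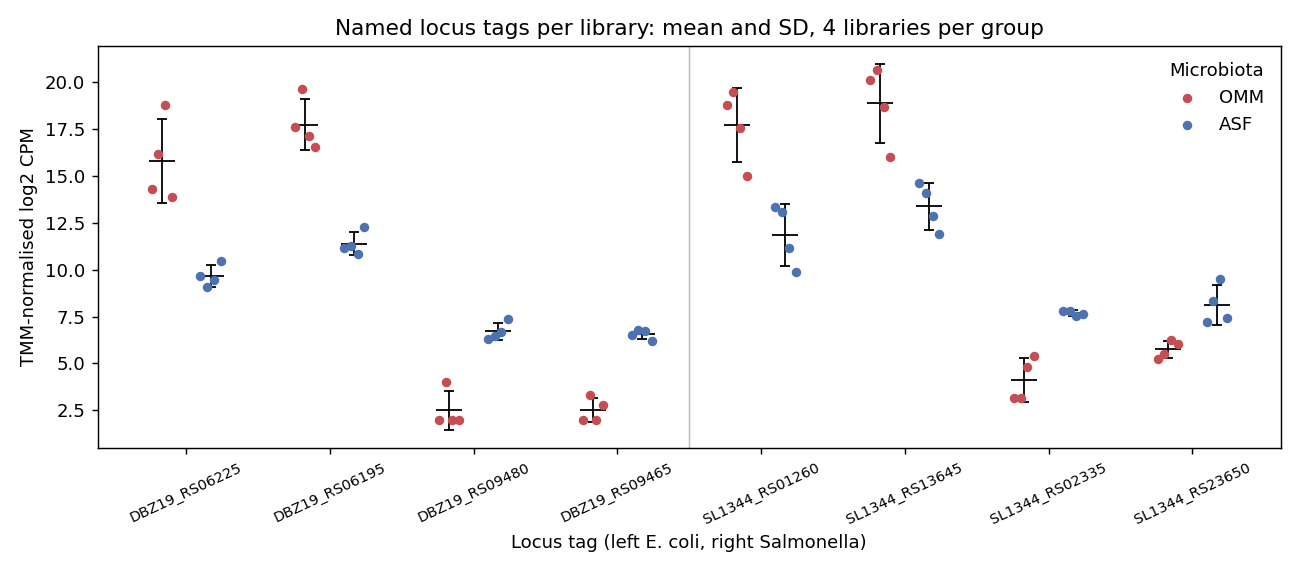
TMM-normalised log2 CPM (y axis) of the 8 named locus tags (x axis, E. coli left of the line and Salmonella right), 1 point per library, with mean and SD of the 4 libraries per background. The OMM and ASF points of a tag do not overlap, which the naming rule requires, and the low OMM points of DBZ19_RS09480 and DBZ19_RS09465 are libraries with 0 to 2 counts.

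The dominant ASF tag of Salmonella also differed as a share of counts (exact two-sided permutation p = 0.0286, n = 4 each; Benjamini-Hochberg p = 0.04 over the same 14 tests). Its log2 fold change after TMM scaling was −2.22 (SE 0.82, edgeR adjusted p = 0.298), and DESeq2 called 1 of the 7 abundant Salmonella tags lower. As in E. coli, the rise of the 4 abundant tags lowers all other shares, so the fall of the dominant share is not independent of it. How much of the fall goes beyond that rise was not measured. The 4 abundant tags that rose had edgeR adjusted p from 0.00478 to 0.00583. With no filter on low counts, 2 of these 4 were called.

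ASF Salmonella replicate 3 was spread as evenly as the 2 ASF E. coli libraries, with 50% of its counts outside the abundant tags on 21.4% of tags against 1.87% to 5.69% in the other 7 Salmonella libraries. Without it, 8 tags were higher and 10 lower, and 11 of these 18 were among the 14. The count was 33 with DESeq2, 36 with no filter and 5 without the abundant tags. In that last setting only 5 of the 14 calls were still among the tags tested, and 4 of them were kept. Without ASF replicate 4, 4 tags were called, all lower, and the calls of SL1344_RS01260 and SL1344_RS13645 ended (edgeR adjusted p = 0.0656 and 0.0928), as they did with no filter on low counts (0.141 and 0.302). Their log2 fold changes were then 5.63 and 5.61 without the library and 5.80 and 5.74 with no filter. The call of SL1344_RS23650 ended without OMM replicate 1, 2 or 4 (edgeR adjusted p = 0.0704, 0.0589 and 0.0556), at log2 fold changes of −2.53, −2.61 and −2.85. All 4 ASF Salmonella libraries and no OMM Salmonella library follow the title series, so for Salmonella a sequencing run and the microbiota cannot be told apart. OMM replicates 2, 3 and 4 all carry S number 2. The OMM Salmonella libraries may thus come from several runs, and their spread may include differences between runs.

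**Figure D3:**
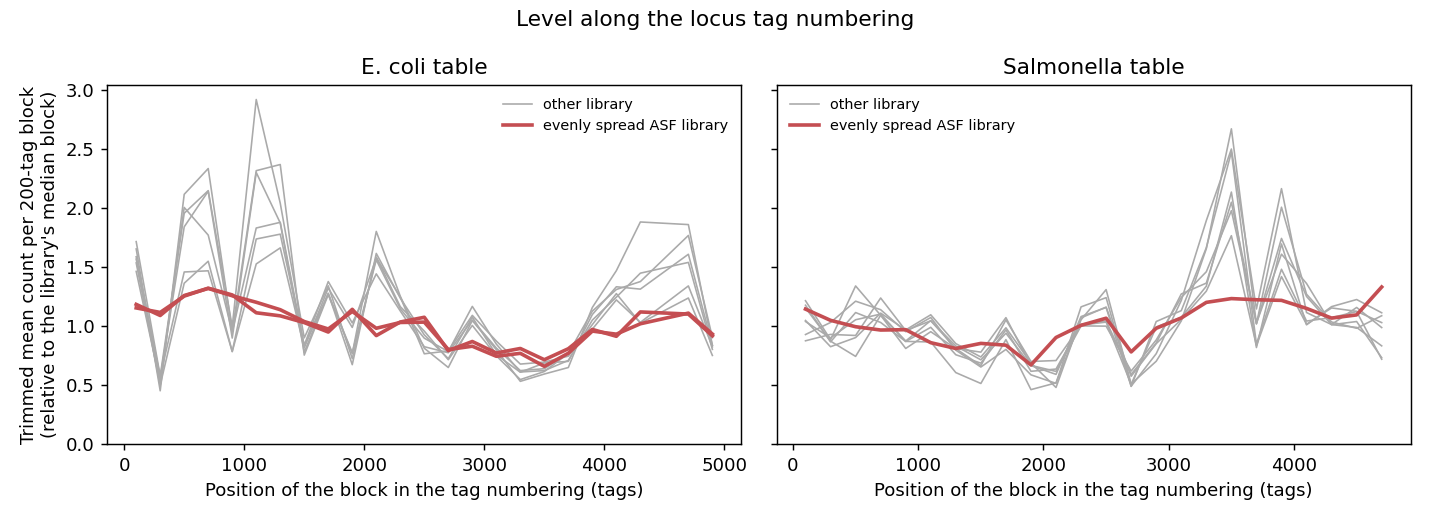
Trimmed mean count per block of 200 tags, relative to the library's median block (y axis, linear), along the order of the locus tags (x axis, tags), 1 line per library, E. coli left and Salmonella right. The 3 evenly spread ASF libraries (red) follow a smoother line than the other 13 (grey).

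Whether E. coli and Salmonella differ in their response to the background was not tested, since the tags of the 2 strains carry no shared gene names here.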

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

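All tests of this part, including the measures of spread, the split of the samples and the fit along the tag numbering, were written down after the results they bear on had been seen.

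In each of 40 groups of 4 values the highest and lowest were compared with the rest by Dixon's test, and 7 stood apart, where chance gives about 1 in 20. OMM E. coli replicate 3 detected 2900 tags (2899.6 as the mean of the draws) at equal depth and held 50% of its counts outside the abundant tags on 1.67% of tags, both the lowest of its group. OMM Salmonella replicate 4 held 110819 counts outside the abundant tags, against 12216 to 22220 in the other 3. ASF Salmonella replicate 3 had 476703 counts in all, detected 3888 tags at equal depth (3887.6 as the mean of the draws) and spread 50% of its counts outside the abundant tags over 21.4% of tags, each the highest of its group. For DBZ19_RS09480, OMM E. coli replicate 2 stood at 4.03 log2 CPM, from 2 counts where the other 3 OMM libraries had 0. With 3 values at the same floor any other value stands apart, so this 1 of the 7 says nothing.

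For the number of E. coli tags called between backgrounds, 1 of the 35 splits of the 8 libraries into 4 and 4 gave as many as the real one, namely the real one itself, with 58 against at most 1 in any other split. For Salmonella it was also 1 of 35, with 14 against at most 1. A share of 1 in 35 is the smallest this test can give, and the test was chosen after the calls had been seen. Mixed splits also put the difference between backgrounds into the spread within groups, so few calls there are no surprise. The splits ignored the title series, and E. coli splits that keep its balance are fewer. The real split thus gave the most calls in each organism, but chance assignment of libraries to groups is not excluded.

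Evenly spread counts mark ASF E. coli replicates 1 and 2 and ASF Salmonella replicate 3, where 50% of counts outside the abundant tags lay on 21.3% to 21.4% of tags against 1.67% to 5.69% in the other 13 libraries. Depth is argued against, since at equal depth these libraries still detected at least 1.32 times as many tags as any other library of their organism. The run that the title series marks stays open: all 3 evenly spread libraries belong to the series and 0 of the 8 libraries outside it are evenly spread, while 5 of the 8 libraries of the series are not. Reads from genomic DNA are a candidate explanation, since copy number in growing cells falls smoothly from replication origin to terminus. A single cosine along the tag numbering gave an R2 of at least 0.671 in these 3 libraries and at most 0.38 in the others. But these libraries were picked for even counts. Their highest block of 200 tags was 1.85 to 2 times the lowest, against 3.1 to 5.78 times in the others. Less unevenness between blocks can raise R2 by itself, so this comparison does not decide. Evenly low transcription may follow copy number too, and a difference in the state of the bacteria between mice or backgrounds stays open, untested.

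The abundant tags higher in OMM may reflect the scaling of the libraries, reads of other bacteria, uneven removal of such RNA, a step the labels do not mention, or the bacteria themselves. As shares of counts without size factors, the 4 E. coli tags held 33.5% to 77.5% in OMM and 0.514% to 1.67% in ASF. The 4 Salmonella tags held 22.6% to 88.0% and 0.786% to 6.28%, so size factors alone did not make the difference. All 8 tags were chosen by their calls under TMM, and RLE and DESeq2 size factors also called all 8 higher. These scalings all assume that most tags do not change, so an error they share was not tested. With no filter on low counts 0 of the 4 E. coli and 2 of the 4 Salmonella tags were called. The comparison was narrowed to the scalings after that value of 2 had been seen, because a filter is not a scaling. With no filter the log2 fold changes of DBZ19_RS06225 and DBZ19_RS06195 were 7.50 and 7.02, against 7.32 and 6.78 with it. Reads of other bacteria on conserved sequences would not rise and fall with the counts on other tags, and the ratio of these tags to counts outside the abundant tags varied 6.92-fold among the OMM E. coli libraries and 23.7-fold among the OMM Salmonella libraries, but uneven removal of abundant RNA gives the same, so these cannot be told apart without gene names or the control samples. A difference of the bacteria between backgrounds stays open and untested.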

How the results depend on the processing

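RLE size factors and a 2-fold minimum left the counts of calls at 58 in E. coli and 14 in Salmonella, and RLE shared 56 and 14 of them. The E. coli count was 269 with DESeq2 (58 shared), 38 with no filter (21 shared), 92 with the filter at fixed counts (1825 tags tested), 95 with the title series as a covariate, 1894 inside the series and 23 outside it. Leaving out 1 library gave 33 (without ASF replicate 2) to 134 (without ASF replicate 3). The Salmonella count was 33 with DESeq2, 36 with no filter and 5 with the abundant tags left out, a setting chosen after seeing the data that tested 569 tags. Only 5 of the 14 calls could still be tested in that setting, and 4 of them were kept. Leaving out 1 Salmonella library gave 4 (without ASF replicate 4; 0 higher, and 98 tags at an unadjusted edgeR p below 0.05) to 18, and the filter at fixed counts called 8 higher and 5 lower. The median log2 fold change of E. coli tags was −0.13 with TMM and filterByExpr and −0.63 with TMM and no filter. With DESeq2, also run without filterByExpr, it was −0.83. Most of the difference between −0.13 and −0.83 thus goes with the filter rather than with the scaling. The cause of the moves in the counts of calls was not tested. Of the named tags none reversed, and DBZ19_RS09480, DBZ19_RS09465 and SL1344_RS02335 kept their calls under every alternative run (highest adjusted p 0.0408, 0.0431 and 0.0211 in edgeR fits). The others lost calls only as the report gives, with highest edgeR adjusted p of 0.123 for DBZ19_RS06225, 0.109 for DBZ19_RS06195, 0.141 for SL1344_RS01260, 0.302 for SL1344_RS13645 and 0.0704 for SL1344_RS23650. The difference in E. coli totals was −412885 to −269252 with 1 library left out, with exact permutation p = 0.0571 whenever an OMM library was left out. That in Salmonella totals, −42342, became 43305 without ASF replicate 3 and lay between −77259 and that value. Gene list tests, the comparison of organisms and the removal of ribosomal and transfer RNA were not run, for lack of gene names. No paired analysis was possible because replicate numbers follow sample order and no label pairs single samples across groups. The title series, read as a run, links sets of E. coli libraries across backgrounds, and it was fitted as a covariate. Within the ASF E. coli libraries it cannot be told apart from the even spread. Outside the abundant tags the shallowest Salmonella library held 12216 counts and the shallowest E. coli library 32023.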

Other observations

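All tests of this part were chosen after the calls had been seen.

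Tags that neighbour each other in the numbering fell together in E. coli. Among the 58 called tags, 11 pairs of direct neighbours went the same way. In 10000 shuffles of the calls over the tested tags the mean was 0.551 and the highest 5 (permutation p = 1e-04, the smallest these shuffles can give). All shuffles of this part treat tags as independent, while neighbouring bacterial genes in an operon are transcribed together. Calls may thus cluster whatever their cause, and these p-values do not measure the spread between libraries. Over the whole numbering, the longest run of direct neighbours called lower in OMM was 7 tags. In 1 stretch of 20 consecutive tags, which holds DBZ19_RS09480 and DBZ19_RS09465, 12 were called lower in OMM, where shuffling gave at most 5 in any stretch. The whole stretch stood at 123 ± 27.6 normalised CPM in OMM and 1469 ± 106 in ASF (SD, n = 4 each), 12.0-fold apart, a value that is not independent of the calls that chose the stretch. In Salmonella the result depends on what counts as a neighbour: the 14 called tags formed 0 such pairs in the order of all tags, and 2 pairs in the order of the tested tags alone, against a shuffled mean of 0.108 (permutation p = 0.005). Counted over tested tags alone, E. coli had 18 pairs against a shuffled mean of 1.03.

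For these neighbouring E. coli tags, loss of the segment from all E. coli cells of the OMM mice was not excluded: the OMM libraries held 9 to 32 counts on the 12 called tags against 595 to 1179 in the ASF libraries, and how many counts misplaced reads could give was not measured. The evenly spread ASF libraries are argued against as the source, since ASF without them was still 12.6-fold above OMM. Loss from all or part of the cells, and lower transcription in OMM as a biological difference of the backgrounds, stay open.

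Without the evenly spread libraries, 26 neighbouring pairs of E. coli tags went the same way. The longest run called higher in OMM, over the whole numbering, was then 7 tags. Another stretch of 20 tags held 10 tags called higher in OMM. It stood at 1540 ± 634 normalised CPM in OMM (SD, n = 4) and 193 ± 15.5 in the 2 remaining ASF libraries, and over all 4 ASF libraries at 599 ± 479. These values are not independent of the calls that chose the stretch.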
